A study of Mus musculus with 9 samples.

How the data were processed

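Spinal cord tissue of wild-type C57BL/6 mice was sampled on day 7 from sham animals, animals with spinal cord injury (SCI) and injured animals given hyperbaric oxygen (HBO), with 3 RNA-seq libraries per group and 9 in total. Per the labels, RNA was extracted with Trizol and the TransZol Up Plus RNA Kit, and libraries were made from 1 ug of total RNA by standard Illumina protocols. The labels do not say whether the 3 libraries of a group come from separate animals. Oxygen pressure, session number, lesion level and read length are not given in the sources used here.

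Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm38 (mm10). The HISAT2 version, the counting tool, its strand setting, the annotation release and any filter applied by the authors are not given in the sources used here. The deposited count column holds the authors' raw read counts per gene, as whole numbers, for 34745 Ensembl genes in each library. The deposited FPKM column holds the authors' FPKM for the same genes, and was used only for a check. The gene length implied by count and FPKM was the same in every library (largest relative spread 9.5e-05 over 15764 genes with 10 counts or more in every library, median length 5072 bp). In 0 genes was only 1 of the count and the FPKM 0.

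Library totals were 12597119, 11159587 and 13496372 counts in sham, 15715484, 14348650 and 13726337 in SCI, and 14142161, 12708477 and 12463783 in HBO. A count was found for 24929 genes in at least 1 library. Between replicates the chi-squared statistic per degree of freedom was 11.8 to 37.4, so the spread between libraries exceeded counting noise. Ratios for genes with 1 to 3 counts in a group are given with a counting interval at the 95% level from the exact conditional binomial.

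Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups (17901 genes), scaled by TMM, and fitted with glmQLFit in a model with 1 mean per group over all 9 libraries. The 3 contrasts, SCI vs sham, HBO vs SCI and HBO vs sham, were tested with glmQLFTest, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p values of genes are from edgeR unless DESeq2 is named. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM from the edgeR function cpm on TMM-scaled library sizes, as mean ± SD of 3 libraries, and log2 CPM carry a prior count of 2. Where 67 gene IDs share a symbol with another ID, the ID with the highest count kept the symbol. Coordinates are those of the deposited files on GRCm38.

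Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 36 lists. As alternatives, the correlation within each list was estimated from the data, and fry was run. The lists hold 471 entries, of which 470 were in the files (Ahsp was not). They are homeostatic microglia, phagocyte lysosome and activation, monocyte-derived macrophages, neutrophils, T and B lymphocytes, reactive astrocytes, homeostatic astrocytes, myelin and oligodendrocytes, oligodendrocyte precursors, neurons and synaptic vesicles, transmitter synthesis, transport and reception, endothelium and blood-brain barrier, fibroblasts and extracellular matrix, Schwann cells, ependymal cells, erythroid cells, skeletal muscle, bone and cartilage, cell division, cytokines and chemokines, inflammasome and pyroptosis, complement, type I interferon response, antigen presentation, antioxidant and NRF2 response, hypoxia response, oxidative phosphorylation, mitochondrially encoded genes, apoptosis, autophagy, endoplasmic reticulum stress, neurotrophic factors and receptors, axon regeneration, immediate early genes, cholesterol synthesis, and matrix proteases and inhibitors. Members were counted over all genes tested and with p values adjusted over the list alone.

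Named genes followed a fixed rule. For each comparison they are the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap, with a mean of 5 CPM or more in the higher group and a symbol other than predicted, Rik, pseudogene or receptor-segment names. To these were added up to 4 members of each list with the smallest p, and a panel of Gfap, Aif1, Cd68, Mbp, Snap25, Col1a1, Hmox1, Vegfa, Il1b and Bdnf. The lists, this rule, the tests of the 3 comparisons and most alternatives were chosen before the data were examined.

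The relation of the contrasts, which share libraries, was set beside 100 simulated data sets without any group effect. Another 10 such sets, drawn separately, were put through the full model. After the data were examined 100 more were added, with the injury effect kept and HBO equal to SCI. The gene test was tested on simulated data, with negative binomial counts drawn independently per gene from the fitted means and dispersions and fold changes of 1.5, 2 and 4 added. Over SCI vs sham, HBO vs SCI and HBO vs sham it recovered 10.4%, 7.46% and 4.48% of genes changed 1.5-fold, 41.8%, 58.2% and 46.3% of those changed 2-fold and 84.8%, 95.5% and 86.4% of those changed 4-fold. In these sets 17713, 17697 and 17688 genes were tested, and 5 of 99, 13 of 122 and 2 of 94 calls were false. A list of 15 genes changed 1.5-fold was found in each contrast (adjusted p = 1.98e-23, 1.43e-18 and 3.16e-11), with 0 of 35 unchanged lists called. Since the drawn genes are independent, this says nothing on correlated lists.

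Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors in edgeR, no filter on low counts, a mean of 5 CPM or more, replicate number as a block, only the 2 groups compared, each library left out in turn, and an absolute log2 fold change of 1 or more. After the data were examined, 3 more were added: leaving out 1 library per group that stood apart, leaving out genes at ribosomal repeats and mitochondrial genes before scaling, and library totals without TMM. A change of pseudocount does not enter a test on counts and was not run. Exon overlaps between genes came from GENCODE vM21 on GRCm38, with GenomicRanges 1.54.1 and rtracklayer 1.62.0. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the reported comparisons, and reads were not used here.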

Results

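Injury, and injury followed by hyperbaric oxygen, were each compared with sham surgery, and the injured groups were compared with each other. The question is what hyperbaric oxygen changes in the injured cord on day 7. Values are mean CPM ± SD of 3 libraries per group, and log2 fold changes are given ± SE. Since the labels do not say whether libraries come from separate animals, p values measure only the spread between these samples.

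The libraries parted by injury. The first principal component held 63.6% of the variance, with sham at -84.5, -77 and -56.6, SCI at 64.1, 34.3 and 21, and HBO at 12.9, 55.8 and 30. Correlations of log2 CPM were 0.970 to 0.981 within groups, 0.962 to 0.982 between HBO and SCI, and 0.884 to 0.961 between sham and the injured groups. Several libraries carried tissue signals their group did not share. SCI replicate 1 was high in skeletal muscle genes (list mean 5.87 log2 CPM, against 3.15 and 0.39 in the other SCI libraries) and erythroid genes (6.15, against 4.89 and 4.31). Muscle genes were also high in SCI replicate 2 (3.15, with sham at -0.32 to 1.27) and in HBO replicate 1 (3.4, against 1.29 and 0.3). Sham replicate 3 was high in Schwann cell genes (4.17, against 1.18 and 1.35). HBO replicate 3 was high in neutrophil genes (4.77, against 2.91 and 2.09) and held 6.55% mitochondrial counts, against 2.97% to 4.07% in the other 8 libraries.

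**Figure D1:**
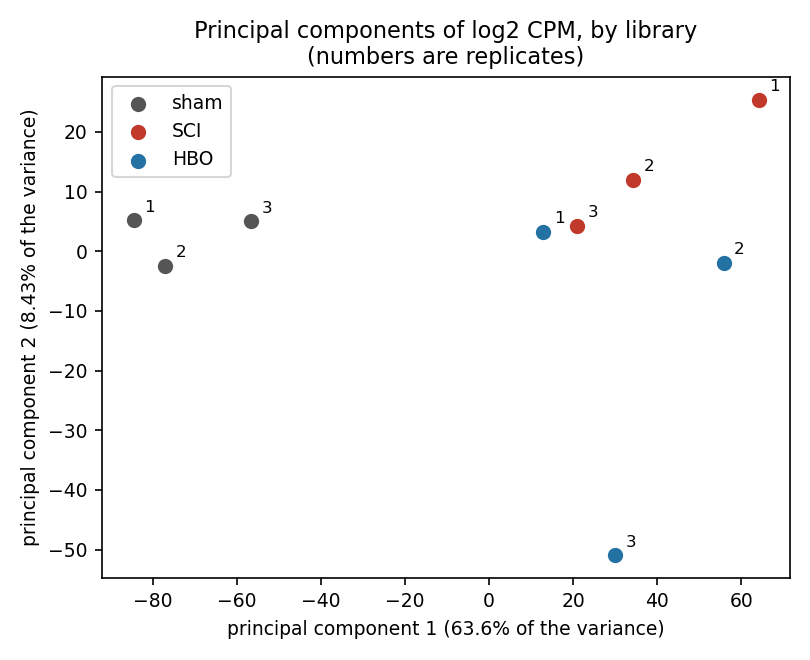
Principal components of log2 CPM over 9 libraries. The first component (63.6%) parts sham from the injured groups and the second (8.43%) parts HBO replicate 3, at -50.9, from the rest.

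In SCI vs sham, genes of scar matrix, phagocytes and dividing cells rose while neuronal genes fell. Fibrillar collagen genes rose: Col3a1 from 47 ± 30.3 to 1910 ± 787 CPM and Col1a1, the main chain of scar collagen, from 118 ± 62.6 to 3010 ± 1310 CPM. Cd68, a lysosomal protein of phagocytes, rose 9.88-fold, and Igf1, a growth factor made by activated microglia and macrophages, rose 8.7-fold. Snap25, needed for release of synaptic vesicles, fell from 1640 ± 143 to 641 ± 194 CPM. In all 6545 of 17901 genes changed (3578 rose, 2967 fell), of which 2008 rose and 836 fell more than 2-fold. Groups did not overlap in 9658 genes (54%, where chance gives 10%).

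The largest rises included matrix genes. Col3a1 (chromosome 1, 45311538 to 45349706) had a log2 fold change of 5.34 ± 0.57 (adjusted p = 0.000516). Postn, a matricellular protein of scar fibroblasts (chromosome 3, 54361109 to 54391037), rose by 5.19 ± 0.41 (adjusted p = 0.000507). Dnm3os, the host transcript of microRNAs active in fibrosis, rose by 5.95 ± 0.65, and Prg4, a lubricating proteoglycan, by 5.62 ± 0.68. The embryonic muscle myosin Myh3 rose by 5.03 ± 1.46, beside the high muscle values of SCI replicate 1. A few of the top genes were near 0 counts in sham. The smooth muscle actin Actg2 had 273 counts in SCI and 1 in sham (ratio 232, counting interval 41.3 to 9210). The hypertrophic cartilage collagen Col10a1 had 318 and 3 (ratio 90.2, 30.6 to 440), and the cardiac actin Actc1 235 and 3 (ratio 66.6, 22.5 to 325). SCI replicate 1 held most of the last 2, with Col10a1 at 17.7 CPM against 1.32 and 1.94 in the other SCI libraries and Actc1 at 12.7 against 2.5 and 0.288, and the counting interval does not cover this spread. Actg2 was at 10, 6.03 and 2.3 CPM.

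Among the falls, Prlr, the prolactin receptor (chromosome 15, 10177238 to 10349180), went from 22.3 ± 1.62 to 3.18 ± 1.2 CPM (log2 fold change -2.81 ± 0.4, adjusted p = 0.000945). Calca, the gene of calcitonin gene-related peptide in sensory and motor neurons, changed by -2.29 ± 0.38, and the neuropeptide Y receptor Npy2r by -1.91 ± 0.31. Gpr21, an orphan receptor, changed by -2.96 ± 0.58, the synaptic adaptor Sh2d5 by -2.23 ± 0.35 and the glucocorticoid-activating enzyme Hsd11b1 by -1.9 ± 0.26. Moap1, an apoptosis adaptor, had 4 counts in SCI and 558 in sham (ratio 0.0061, interval 0.00166 to 0.0157). Since 87.7% of its exon bases are shared with Gm20604 on the same strand, the count of Moap1 is uncertain. Lemd1 (-2.14 ± 0.6) shares 37.7% with other genes and is uncertain too. Of the panel, Gfap, the astrocyte filament, rose by 0.95 ± 0.22 and the microglial Aif1 by 1.18 ± 0.22, and the angiogenic factor Vegfa fell (-0.68 ± 0.21). Mbp (0.18 ± 0.28, adjusted p = 0.664), Il1b (-1.79 ± 0.99, adjusted p = 0.181) and Bdnf (-0.59 ± 0.23, adjusted p = 0.0632) did not pass. The sign of Il1b rests on sham replicate 1 (19.9 CPM, against 1.85 and 0.592 in the other sham libraries), without which it was 0.84, and Mbp was at -0.18 without SCI replicate 1.

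Gene groups of immune cells and scar moved together. With camera 24 of 36 lists passed in SCI vs sham, 19 higher and 5 lower. With a correlation estimated per list 0 passed (lowest adjusted p = 0.262), and with fry 28 passed. Of phagocyte lysosome and activation genes 18 of 18 rose, over all genes and adjusted over the list alone (median log2 fold change 2.41, adjusted p = 1.75e-22, adjusted p = 0.262 with an estimated correlation), with Ctsd, a lysosomal protease, at 5240 ± 1300 against 781 ± 177 CPM and Lyz2, the lysozyme of myeloid cells, 14-fold higher. Ctsd shares 34.4% of its exon bases with another gene and its level is uncertain. Of fibroblast and extracellular matrix genes 15 of 15 rose (median 3.3, adjusted p = 1.02e-18, 0.262 with an estimated correlation). Of complement genes 10 of 13 rose and 12 adjusted over the list alone (2.13, adjusted p = 1.23e-11, 0.262 with an estimated correlation), among them the opsonin subunit C1qa (4.38-fold). Of cell division genes 15 of 15 rose (2.05, adjusted p = 1.18e-10, 0.315 with an estimated correlation), with the topoisomerase Top2a 5.36-fold higher. Of monocyte-derived macrophage genes 10 of 12 rose (2.3, adjusted p = 1.73e-06, 0.315 with an estimated correlation), and of homeostatic microglia genes 8 of 12 (1.16, adjusted p = 8.32e-07, 0.262 with an estimated correlation). Reactive astrocyte genes rose in 11 of 13 (1.46, adjusted p = 4.53e-06, 0.315 with an estimated correlation), with the intermediate filament Vim 3.59-fold higher.

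Neuronal and lipid synthesis groups fell. Of genes of neurons and synaptic vesicles 15 of 15 fell (median -1, adjusted p = 5.64e-08, 0.315 with an estimated correlation). Of transmitter synthesis, transport and reception genes 10 of 15 fell and 12 adjusted over the list alone (-1.23, adjusted p = 6.81e-07, 0.315 with an estimated correlation), among them Gad2, which makes GABA (2.57-fold lower). Of cholesterol synthesis genes 13 of 14 fell and 14 adjusted over the list alone (-0.78, adjusted p = 6.03e-06, 0.339 with an estimated correlation). Oxidative phosphorylation fell in 8 of 17 genes (-0.42, adjusted p = 0.00119, 0.418 with an estimated correlation). Of myelin and oligodendrocyte genes 3 of 14 fell, with Opalin of mature oligodendrocytes at -1.17 ± 0.2 (list median -0.25, adjusted p = 0.0324, 0.468 with an estimated correlation).

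The other called lists of SCI vs sham were all higher. Antigen presentation rose in 10 of 12 genes and 12 adjusted over the list alone (median 1.22, adjusted p = 2.25e-05, 0.315 with an estimated correlation), inflammasome and pyroptosis in 9 of 11 (1.16, adjusted p = 8.31e-06, 0.315), and matrix proteases and inhibitors in 9 of 12 and 10 adjusted over the list alone (2.04, adjusted p = 4.53e-06, 0.315), the last value of each being the adjusted p with an estimated correlation. In the same order of values, apoptosis rose in 10 of 15 (0.76, 0.000347, 0.315), endothelium and blood-brain barrier in 10 of 15 (0.45, 0.000517, 0.315), and endoplasmic reticulum stress in 8 of 12 (0.7, 0.00462, 0.315). Schwann cell genes rose in 6 of 10 and 9 adjusted over the list alone (1.9, 0.00032, 0.326), with a median of 2.6 without sham replicate 3, where these genes were high, and oligodendrocyte precursor genes in 6 of 10 (0.58, 0.0306, 0.315). Of antioxidant and NRF2 genes 8 rose and 3 fell of 18 (0.45, 0.0306, 0.326), with Hmox1, which degrades haem, 11.8-fold higher. Hmox1 reached 286 CPM in SCI replicate 1 and 75.8 and 81.1 CPM in the other SCI libraries. Cytokines and chemokines rose in 7 of 15 (0.69, 0.031, 0.418), erythroid genes in 5 of 7 and 7 adjusted over the list alone (1.83, 0.0098, 0.418), and skeletal muscle genes in 8 of 10 and 10 adjusted over the list alone (4, 0.0398, 0.58). The muscle and erythroid genes stand beside the high values of SCI replicate 1, and without it their medians were 1.81 and 1.01.

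The other 12 lists did not pass with camera in SCI vs sham, of which 5 passed with fry (neurotrophic factors, axon regeneration, autophagy, bone and cartilage, and lymphocytes). Neurotrophic factors and receptors had 8 rises and 2 falls of 13 genes (median 1.33, adjusted p = 0.0724), axon regeneration 5 and 2 of 12 (0.62, 0.14), and immediate early genes 3 and 0 of 11 (0.6, 0.314). The median of immediate early genes was 0.37 without SCI replicate 1. Autophagy had 4 and 1 of 12 (0.01, 0.416), hypoxia response 2 and 2 of 17 (0.18, 0.637), and homeostatic astrocytes 1 and 3 of 12 (-0.17, 0.188). Type I interferon response had 3 rises of 15, and 1 adjusted over the list alone (0.3, 0.188). Bone and cartilage had 3 rises of 6 (0.87, 0.188), with Col10a1, at only 3 counts in sham, among its members. T and B lymphocytes had 2 of 3 (1.41, 0.214) and neutrophils 1 of 11, Csf3r (-0.34, 0.821). Only 3 of the 13 lymphocyte genes passed the filter on counts, so this list says little on these cells. No gene passed of 8 ependymal genes (0.03, 0.73) and 13 mitochondrially encoded genes (-0.03, 0.574). For neutrophils the median and the mean (-0.09) were below 0 and the test pointed up, and for ependymal cells the mean (-0.03) and the test were opposite to the median. The median of neutrophils was 0.13 without sham replicate 1, that of ependymal cells was -0.13, -0.22 and -0.01 without sham replicate 2 and SCI replicates 2 and 3, that of autophagy was -0.01 without SCI replicates 1 or 3, and that of mitochondrially encoded genes was 0.03 without sham replicate 3.

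Without SCI replicate 1, 4316 genes passed in SCI vs sham, and without sham replicate 1, 4401. The calls of 4 lists were lost without single libraries: antioxidant (without SCI replicate 3, median 0.39), cytokines (without sham replicates 2 or 3 or SCI replicate 2, 0.66, 0.53 and 0.61, with 1.46 without sham replicate 1, where the list mean was 1.92 log2 CPM against 0.52 and 0.73 in the other sham libraries), myelin (without sham replicate 2 or SCI replicate 2) and muscle (without sham replicates 2 or 3 or SCI replicate 1, 3.96, 3.81 and 1.81), while neurotrophic factors passed without sham replicate 3 or SCI replicate 1 and interferon response without sham replicate 1 (0.63).

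**Figure D2:**
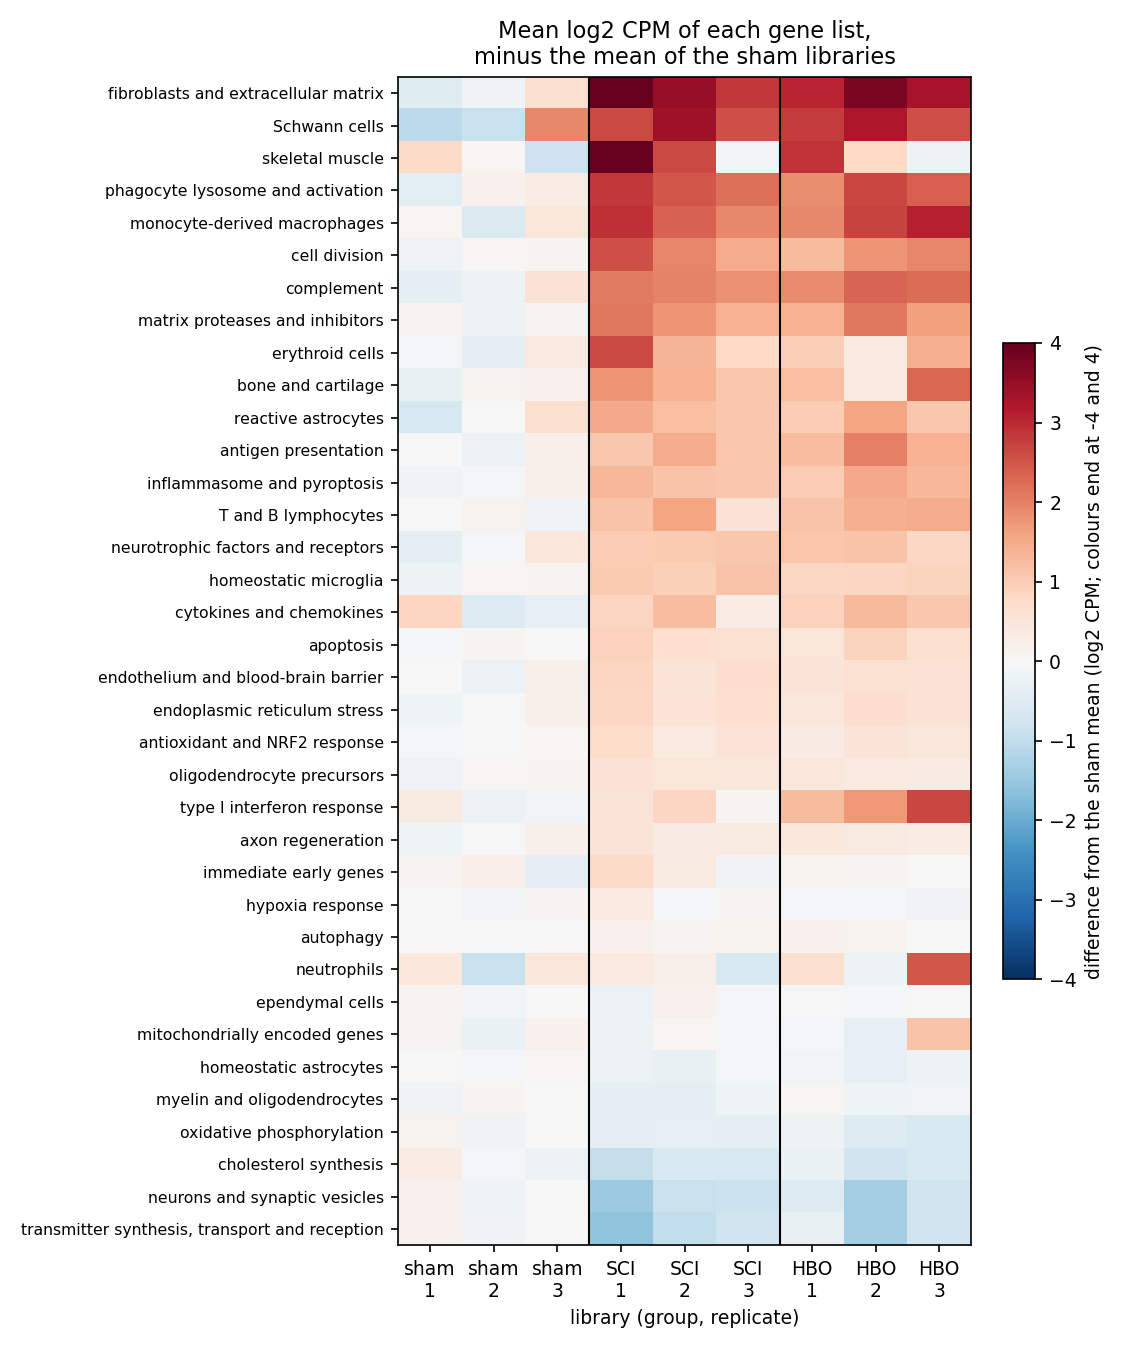
Mean log2 CPM of each of 36 gene lists per library, minus the sham mean. The interferon response list had means of 3.58, 3.9 and 3.15 log2 CPM in SCI and 4.32, 4.79 and 5.71 in HBO.

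In HBO vs SCI, the genes of the type I interferon response stood higher after hyperbaric oxygen, and no gene passed the test over all genes. Ifi44, an interferon-induced gene (chromosome 3, 151730922 to 151749960), was at 18 ± 11.4 CPM in HBO and 4.37 ± 1.18 in SCI. Irf7, the transcription factor that amplifies interferon production (chromosome 7, 141262706 to 141266481), was at 28.8 ± 15.8 and 8.62 ± 2.42 CPM. Usp18, which restrains interferon receptor signalling, was at 17.3 ± 8.09 and 5.14 ± 0.954 CPM. Scar and phagocyte genes were not called, such as Col1a1 at 3050 ± 1120 against 3010 ± 1310 CPM and Cd68 at 188 ± 61.8 against 256 ± 103 CPM.

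With edgeR 0 of 17901 genes passed in HBO vs SCI (lowest adjusted p = 0.806), and 749 (4.18%) had an unadjusted p under 0.05. The DESeq2 Wald test called 26 genes, 25 higher and 1 lower. Groups did not overlap in 1437 genes (8.03%, where chance gives 10%). Leaving out single libraries gave 0 to 4 genes with edgeR: 2 without SCI replicate 1 (Pnma2 and C330011M18Rik), 2 without SCI replicate 3 (Tgfa and Phb), 1 without HBO replicate 1 (Ddx60), 4 without HBO replicate 2 (Prlr, ENSMUSG00000102422, Zfp715 and Ppp1r26) and 1 without HBO replicate 3 (Tmem127). These names, and those of the DESeq2 calls that follow, were chosen after their values were seen. DESeq2 called 6 genes of the interferon list (Ifi44, Ifit1, Usp18, Irf7, Ifi27l2a and Rtp4), and outside it, as higher, Moap1, Zfx, Lgals3bp, Oas2, Pydc4, H2-Q4, H2-Q6, Gm4955, Ddx60, Prlr, F830016B08Rik, Gpr21, Tnfsf10, Slfn8, H2-Q7, Pcdhgb1, Pnma2, Oasl1 and Gm4951. Its lower gene was Gipc1, a trafficking adaptor (log2 fold change -0.49). Its call of Moap1 rests on 4 counts in SCI and on exons shared with another gene, and is uncertain, as is that of Pcdhgb1, which shares 54.6% of its exon bases with other genes.

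All 15 of 15 interferon genes had a positive log2 fold change in HBO vs SCI. None of them passed over all genes, and 15 of 15 passed adjusted over the list alone. The list median was 1.72 (camera adjusted p = 5.23e-41 at the preset correlation, adjusted p = 0.219 with the estimated correlation of 0.82). In 13 of 15 genes every HBO library was above every SCI library, the exceptions being Isg15 and Rsad2. The log2 fold change was 2.04 ± 0.41 for Ifi44, 1.75 ± 0.36 for Usp18, 1.74 ± 0.37 for Irf7 and 1.72 ± 0.36 for Ifi27l2a (adjusted p = 0.806 for each). HBO replicate 3, the library with high neutrophil and mitochondrial counts, had the highest list mean (5.71 log2 CPM, against 4.32 and 4.79), and without it the median was 1.09. The list passed with camera without each of the 6 libraries in turn (median 1.09 to 1.96).

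**Figure D3:**
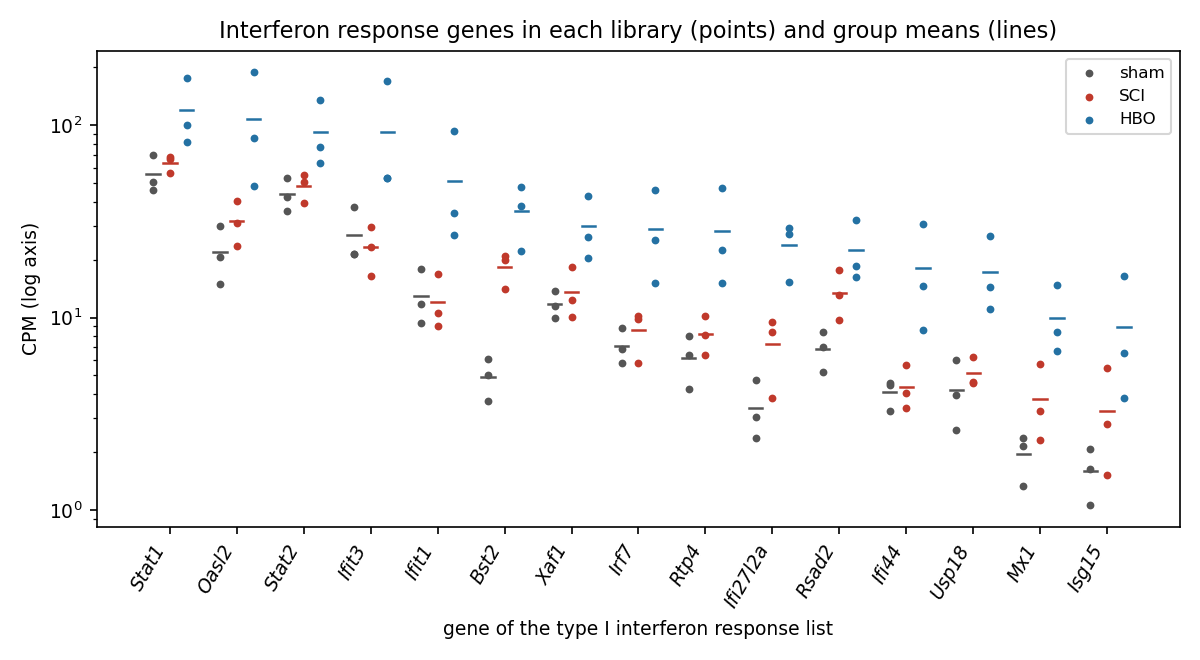
CPM of 15 type I interferon response genes in 9 libraries, with group means. Ifi44 averaged 4.37 CPM in SCI and 18 in HBO.

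In the other lists of HBO vs SCI too, 0 genes passed over all genes. With camera 15 of 36 lists passed, 9 higher and 6 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.219), and with fry 0 (lowest adjusted p = 0.727). Of the 10 splits of these 6 libraries into 3 and 3, the real one included, 6 called 15 lists or more with camera. Antigen presentation was higher (median 0.39, adjusted p = 1.71e-05, 0.728 with an estimated correlation), with B2m, the light chain of class I molecules, at 445 ± 138 against 250 ± 43.8 CPM and 1 gene passing adjusted over the list alone. Myelin and oligodendrocyte genes were higher in 12 of 14 (0.25, adjusted p = 2.29e-05, 0.728 with an estimated correlation), with Opalin at 0.66 ± 0.2. Transmitter genes were higher (0.34, adjusted p = 0.000498, 0.736 with an estimated correlation), as were genes of neurons and synaptic vesicles (0.19, adjusted p = 0.0248, 0.795 with an estimated correlation) and of cholesterol synthesis (0.19, adjusted p = 0.00389, 0.793 with an estimated correlation). Cytokines and chemokines were higher with 1 gene, the monocyte attractant Ccl12, passing adjusted over the list alone (0.2, adjusted p = 0.0412, 0.736 with an estimated correlation). Neutrophil genes (1.55, adjusted p = 1.13e-05, 0.728 with an estimated correlation) and mitochondrially encoded genes (0.44, adjusted p = 0.00396, 0.793 with an estimated correlation) were higher beside the high values of HBO replicate 3, where mt-Atp6 was at 6224 CPM against 456 and 402 in the other HBO libraries. Without that library their medians were 0.14 and -0.12, and the mitochondrially encoded genes passed in the opposite direction, as lower (adjusted p = 0.0427).

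The lists that were lower in HBO vs SCI were skeletal muscle (median -2.23, adjusted p = 0.000123, 0.736 with an estimated correlation) and erythroid cells, with 4 genes passing adjusted over the list alone (-1.09, adjusted p = 0.000274, 0.728 with an estimated correlation). Cell division was lower in 14 of 15 genes (-0.41, adjusted p = 0.00038, 0.736 with an estimated correlation), and immediate early genes in 10 of 11 (-0.36, adjusted p = 0.0156, 0.736 with an estimated correlation). Hypoxia response was lower (-0.18, adjusted p = 0.00393, 0.728 with an estimated correlation), with 1 gene passing adjusted over the list alone, Ankrd37, a target of hypoxia-inducible factor (0.733 ± 0.416 against 2.22 ± 0.179 CPM). Ankrd37 shares 26.4% of its exon bases with other genes. Homeostatic microglia genes were lower (-0.14, adjusted p = 0.0394, 0.728 with an estimated correlation).

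Of these 15 lists, 11 did not pass without SCI replicate 1, the library with the highest muscle and erythroid values, where the medians were -0.03 for muscle, -0.27 for erythroid cells, -0.02 for cell division, -0.08 for immediate early genes, -0.04 for hypoxia, -0.12 for microglia, -0.01 for neurons, 0.15 for transmitter genes, 0.27 for cytokines, 0.33 for mitochondrially encoded genes and 0.1 for cholesterol synthesis. Without HBO replicate 1 the calls of microglia (-0.14), neurons (-0.01), transmitter (0.1), cell division (-0.29) and cholesterol (-0.03) were lost, without HBO replicate 2 those of erythroid (-0.95), cytokines (0.13), antigen presentation (0.05) and immediate early genes (-0.38), without HBO replicate 3 those of neutrophils (0.14) and neurons (0.14), with that of mitochondrially encoded genes reversed (-0.12), and without SCI replicate 3 those of microglia (-0.1) and cytokines (0.06). Other called medians grew by 1.5 times or more: without SCI replicate 2 neurons (0.29), cytokines (0.4), antigen presentation (0.59) and hypoxia (-0.3), without SCI replicate 3 cell division (-0.62) and immediate early genes (-0.56), without HBO replicate 1 muscle (-3.68), and without HBO replicate 2 microglia (-0.22), neurons (0.4), transmitter genes (0.53), mitochondrially encoded genes (0.69) and cholesterol (0.32). Immediate early genes were at -0.21 without HBO replicate 3.

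The remaining 21 lists did not pass in HBO vs SCI. Their medians ran from -0.21 (phagocyte lysosome and activation, adjusted p = 0.0621) to 0.25 (T and B lymphocytes, 3 of 13 genes tested, adjusted p = 0.384). The phagocyte list passed as lower without SCI replicate 2 (-0.22), SCI replicate 3 (-0.38), HBO replicate 2 (-0.43) or HBO replicate 3 (-0.19). Others also passed without single libraries: macrophages as higher (HBO replicate 1, 0.31, and SCI replicate 1, 0.35), inflammasome as higher (0.25) and oxidative phosphorylation as lower (-0.18) without HBO replicate 1, reactive astrocytes as lower (-0.27) and bone and cartilage (0.29) without HBO replicate 2, endothelium (-0.24), antioxidant (-0.07) and endoplasmic reticulum stress (-0.16) as lower without SCI replicate 2, and fibroblasts as lower (-0.28) without SCI replicate 3. Among them were fibroblasts and extracellular matrix (-0.04, adjusted p = 0.431), reactive astrocytes (-0.14, adjusted p = 0.296), antioxidant and NRF2 response (-0.07, adjusted p = 0.384), inflammasome and pyroptosis (0.11, adjusted p = 0.273) and oxidative phosphorylation (-0.07, adjusted p = 0.419). Monocyte-derived macrophages had 1 gene, Ms4a4c, passing adjusted over the list alone (0.09, adjusted p = 0.167). For complement the median (-0.06) was opposite to the mean (0.22) and the test. For bone and cartilage the mean (0.07) was opposite to the median (-0.01) and the test, and for neurotrophic factors the test pointed up with a median of -0.08 and a mean of -0.07. Of the panel Gfap (-0.16 ± 0.22), Aif1 (0.29 ± 0.21), Mbp (0.12 ± 0.28), Snap25 (0.37 ± 0.27), Hmox1 (-1.27 ± 0.46), Vegfa (-0.29 ± 0.21), Il1b (0.77 ± 1.01) and Bdnf (0.08 ± 0.23) did not pass.

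In HBO vs sham, genes of scar and phagocytes rose and neuronal genes fell as in SCI vs sham, and interferon genes rose. Col1a1 rose 25.9-fold, Cd68 7.24-fold and Igf1 11.5-fold (235 ± 85.6 against 20.3 ± 9.64 CPM), while Snap25 fell to 830 ± 264 from 1640 ± 143 CPM. Bst2, an interferon-induced protein that tethers viruses, rose 7.23-fold (35.9 ± 12.8 against 4.93 ± 1.19 CPM). In all 5530 genes changed (3108 rose, 2422 fell), of which 1816 rose and 508 fell more than 2-fold. Groups did not overlap in 8446 genes (47.2%, where chance gives 10%).

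Among the largest rises in HBO vs sham, Col3a1 had a log2 fold change of 5.53 ± 0.58, Dnm3os of 5.74 ± 0.65 and Prg4 of 5.53 ± 0.68. The potassium channel Kcnj15 rose by 6.09 ± 1.4 (adjusted p = 0.00981), the cadherin Fat2 by 5.46 ± 1.07, the organic cation exporter Slc47a1 by 5.44 ± 0.97 and the xylosyltransferase Gxylt2 by 5.29 ± 0.49 (adjusted p = 0.000706). The carboxypeptidase Cpz had 308 counts in HBO and 2 in sham (ratio 146, counting interval 40.1 to 1210). HBO replicate 2 held most of it (17 CPM, against 3.25 and 3.56 in the other HBO libraries), which the counting interval does not cover, and was also highest for Slc47a1 (44.2, against 8.7 and 3.89), Fat2 (15.4, against 3.61 and 3.14) and Kcnj15 (27.6, against 8.84 and 9.43). The falls were Rxfp1, the relaxin receptor (-1.85 ± 0.4), Syt6 (-1.68 ± 0.32), Asphd1 (-1.66 ± 0.34), Crabp1 (-1.64 ± 0.37), Lingo3 (-1.61 ± 0.25), Calca (-1.59 ± 0.36, adjusted p = 0.00965), Slc35d3 (-1.57 ± 0.32) and Moap1 (-2.18 ± 0.51), the last uncertain for its shared exons. Of the panel Gfap (0.79 ± 0.22), Aif1 (1.47 ± 0.22) and Hmox1 (2.3 ± 0.49) rose and Vegfa (-0.97 ± 0.21) fell, and Mbp (adjusted p = 0.452), Il1b (0.447, with a log2 fold change of -1.03, and 1.61 without sham replicate 1) and Bdnf (0.11) did not pass.

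With camera 20 of 36 lists passed in HBO vs sham, 16 higher and 4 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.201), and with fry 26 passed. Type I interferon genes rose in 15 of 15 (median 2.05, adjusted p = 1.43e-09, 0.304 with an estimated correlation) and antigen presentation genes in 12 of 12 (1.84, adjusted p = 1.2e-09, 0.239 with an estimated correlation). Complement rose in 13 of 13 (2.1, adjusted p = 1.76e-14, 0.201 with an estimated correlation), phagocyte genes in 18 of 18 (2.23, adjusted p = 2.87e-23, 0.201 with an estimated correlation) and fibroblast genes in 15 of 15 (3.45, adjusted p = 1.85e-20, 0.201 with an estimated correlation). Cell division rose in 15 of 15 (1.59, adjusted p = 8.56e-09, 0.304 with an estimated correlation). Genes of neurons and synaptic vesicles fell in 11 of 15 and 14 adjusted over the list alone (-0.83, adjusted p = 5.06e-07, 0.304 with an estimated correlation), transmitter genes in 9 of 15 (-0.88, adjusted p = 4.06e-05, 0.336 with an estimated correlation), oxidative phosphorylation genes in 8 of 17 and 15 adjusted over the list alone (-0.46, adjusted p = 0.000118, 0.336 with an estimated correlation), and cholesterol synthesis genes in 7 of 14 and 13 adjusted over the list alone (-0.56, adjusted p = 0.000189, 0.4 with an estimated correlation). The other 10 called lists were higher, with medians from 0.49 (endothelium and blood-brain barrier) to 2.65 (monocyte-derived macrophages), and with adjusted p from 0.201 to 0.304 with an estimated correlation.

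Myelin and oligodendrocyte genes did not pass in HBO vs sham, singly or as a list (median -0.03, adjusted p = 0.517). Their median was -0.14 without HBO replicate 1 and 0.03 without HBO replicate 2. Skeletal muscle (1.84, adjusted p = 0.304, and 0.18 without HBO replicate 1, where these genes were high) and erythroid cells (1 of 7, 0.61, adjusted p = 0.153) did not pass, nor did neutrophils (2 of 11, 1.21, adjusted p = 0.0572), which passed without sham replicate 1, sham replicate 3, HBO replicate 1 or HBO replicate 2 and had a median of -0.05 without HBO replicate 3. Lists also passed without single libraries for antioxidant (HBO replicates 1 or 3), neurotrophic factors (sham replicates 2 or 3, HBO replicates 2 or 3), homeostatic astrocytes (HBO replicate 1, -0.33) and bone and cartilage, erythroid and oligodendrocyte precursor genes (HBO replicate 2). Without sham replicate 1 the number of genes called was 3053, and without HBO replicate 2 it was 3195. The median of cytokines (1.1) was 1.72 without sham replicate 1, that of endothelium (0.49) was 0.74 without sham replicate 3, and those of hypoxia response (-0.03) and mitochondrially encoded genes (0.27) changed sign without HBO replicate 3 (0.06 and -0.24).

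The responses of the injured groups overlapped. Of the 6545 genes of SCI vs sham 4833 (73.8%) also passed in HBO vs sham in the same direction, 2765 higher and 2068 lower, where independent lists would share 621 and 401. In the data 0 genes passed in opposite directions. Simulated data without any effect shared 0 genes in each of 10 draws, but without an effect hardly any gene is expected to pass, so this gives no reference value. The counts for independent lists leave out that both contrasts use the same sham libraries. How much of the overlap comes from these libraries is thus not known. For correlations across genes, which are not independent replicates, log2 fold changes were taken as differences of group mean log2 CPM. Those of SCI vs sham and HBO vs sham had a correlation of 0.934, where shared sham libraries alone gave 0.507 (0.486 to 0.531 in 100 draws). Without sham replicate 1 the shared genes were 2669 and without HBO replicate 2 2962.

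Over the 6545 genes of SCI vs sham, the change in HBO vs sham was smaller or opposite in 4894 (74.8%), and the median change of HBO from SCI, signed by the direction of injury, was -0.118 log2 units. Selecting genes on SCI libraries makes their fold change there too large. With genes selected without 1 SCI library and HBO compared with that library only, the median was -0.355, -0.007 and 0.045 for SCI replicates 1, 2 and 3. SCI replicate 1, the library with high muscle and erythroid values, gives the largest of these. On differences of group mean log2 CPM, the correlation of SCI vs sham with HBO vs SCI was -0.315, the covariance was -0.0803, and 65% of genes had opposite signs. Simulated data without any effect gave -0.491, -0.0419 and 66.5%, and the correlation and the share of signs have no usable value there since the injury effect is missing. With the injury effect kept and HBO equal to SCI they gave -0.168 (-0.198 to -0.138 in 100 draws), -0.0419 (-0.0502 to -0.0348) and 56.1% (55.2% to 57.1%). By these 3 values HBO was more opposed to the injury response than in these draws. For SCI vs sham with HBO vs sham, the correlation (0.934, draws 0.938 to 0.944) and the covariance (0.631, draws 0.673 to 0.697) lay below the draws. The share of genes with the same sign did not (87.5%, draws 86.9% to 88.2%). Since the simulated genes are independent, these ranges do not cover a library that differs in many genes at once, so whether HBO opposes the injury response stays open.

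**Figure D4:**
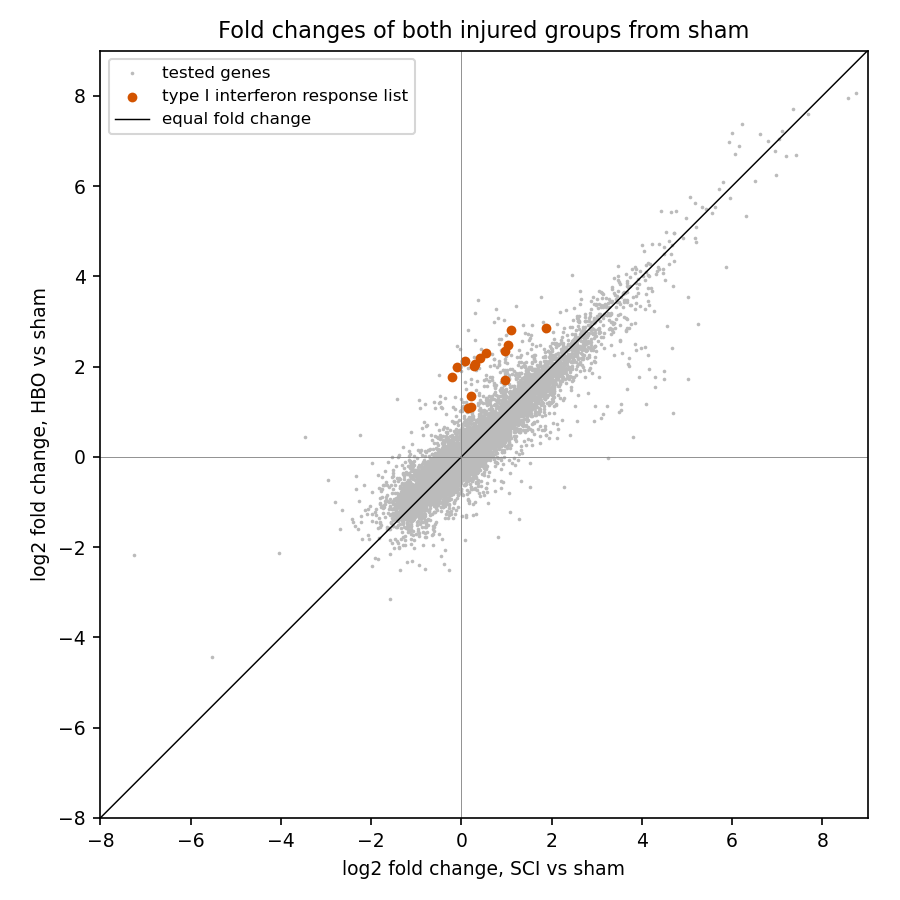
Log2 fold changes from edgeR of SCI vs sham and HBO vs sham for 17901 genes, with the 15 interferon response genes marked. Taken instead as differences of group mean log2 CPM, they had a correlation of 0.934 across genes.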

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

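In HBO vs SCI, 15 gene lists differed between the groups by camera with its preset correlation, and this is what marks them for a closer look; no list differed with an estimated correlation or with fry. The tests of HBO replicate 3, of neutrophil content, of the interferon list against other genes within each library and of the splits for the number of genes in HBO vs SCI were chosen only after the result was seen. The list medians (log2 fold change) were 1.72 for type I interferon response, 1.55 for neutrophils, 0.44 for mitochondrially encoded genes, 0.39 for antigen presentation, 0.34 for transmitter genes, 0.25 for myelin and oligodendrocytes, 0.2 for cytokines and chemokines, and 0.19 for both neurons and synaptic vesicles and cholesterol synthesis. They were -2.23 for skeletal muscle, -1.09 for erythroid cells, -0.41 for cell division, -0.36 for immediate early genes, -0.18 for hypoxia response and -0.14 for homeostatic microglia. The list means of HBO and SCI libraries did not overlap in 3 of these lists (interferon response, myelin and homeostatic microglia). Chance gives this in 10% of comparisons of 3 with 3 libraries, and these 15 lists were picked for differing. Oligodendrocyte precursors, which camera did not call, did not overlap either (6.66 to 6.8 log2 CPM in HBO, 6.81 to 6.91 in SCI).

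Interferon response genes were higher in HBO than in SCI. The tables argue against HBO replicate 3 as the only source, since the median without it was 1.09, and the other HBO libraries lay 1.01 (SE 0.32) log2 units above the SCI mean. They argue against 1 wrong factor per library for all genes too, since the list mean minus the median of the other tested genes in the same library, which no such factor changes, was 1.42 (SE 0.46) higher in HBO. The 3 scalings run (lowest list median 1.72) decide nothing on this, as the median of all genes lay between -0.006 and -0.003 under each. Neutrophil content stays open: the neutrophil list of HBO replicates 1 and 2 lay 0.22 (SE 0.51) above the SCI mean, which is too wide to decide, and HBO replicate 3 had the highest values of both lists. The 10 splits of the 6 libraries are too few for a share under 0.05 (1 split as large, real median 1.72, highest other 1.23), and an effect of oxygen treatment may be among the causes but cannot be told apart from differences between these samples.

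Neuronal genes were slightly higher in HBO than in SCI (median 0.19). Without SCI replicate 1, and without HBO replicate 1, the median was -0.01, as an unequal share of lesion tissue in single libraries would predict. But these were the lowest SCI library and the highest HBO library for this list (list means 7.6 and 8.51 log2 CPM). Leaving out either lowers the difference whatever its cause, and lesion share was not measured, so this cannot decide. Without HBO replicate 2 (7.68 log2 CPM) the median was 0.4. Of the 10 splits 5 were as large, the real one included (real value 0.19, highest other 0.49). Splits that mix the groups thus gave medians as large, so the size of this difference does not set HBO apart from SCI. An effect of the treatment stays open and was not tested apart from differences between these libraries.

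Large single-gene differences between HBO and SCI outside the interferon list (31 genes with an unadjusted p under 0.01, a log2 fold change of 1.5 or more in size and 2 CPM or more, picked for these values) include several whose exons overlap another gene, such as Moap1 (87.7% of exon bases) and Pcdhgb1 (54.6%). Overlaps were found in 13 of 31 (41.9%) against 6258 of 17786 other tested genes (35.2%), an odds ratio of 1.33 (0.599 to 2.87, one-sided Fisher's exact p = 0.271). The interval is too wide to decide whether shared reads could be a source of this pattern. Of those without overlaps, Tmem127 was at 138.71 and 137.97 CPM in HBO replicates 1 and 2 against 18.36 in replicate 3.

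For the number of genes and lists called, the 10 splits of the 6 libraries in each comparison are too few for a share under 0.05. In SCI vs sham the real split called 6545 genes and the highest other 1 (1 split as large), and 24 and 22 lists (1 as large). In HBO vs sham the values were 5530 and 0 genes (1 as large), and 20 and 22 lists (2 as large). In HBO vs SCI they were 0 and 4 genes. With a real count of 0 all 10 splits are as large by construction, which tests nothing. Lists numbered 15 and 18 there (6 as large). Splits that mix the groups thus called up to nearly as many lists, or more, by camera with its preset correlation, in each comparison.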

How the results depend on the processing

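The settings with 2 libraries per group, without ribosomal-repeat and mitochondrial genes, and with library totals only were chosen only after the data were seen. In no setting did a called gene of SCI vs sham or HBO vs sham reverse, and no named gene changed sign where it passed, or had passed, the threshold. DESeq2 kept 6418 of 6545 and 5431 of 5530 genes.

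With each library left out in turn, SCI vs sham had 4316 to 5913 genes (1700 to 2545 lower), HBO vs SCI 0 to 4 (0 to 2 higher, 0 to 3 lower) and HBO vs sham 3053 to 5777 (2066 to 3134 higher, 987 to 2643 lower). Lists called in HBO vs SCI ran from 5 to 19, and genes shared by both injured groups from 2669 to 4875. Fewer libraries leave fewer degrees of freedom, and which property of each library moved the counts was not tested.

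With 2 libraries per group, SCI vs sham had 3477 genes (2270 higher, 1207 lower), HBO vs SCI 2 (1 higher, 1 lower; Tmem127 and Usp49, named after their values were seen), the lower genes of HBO vs sham were 1434, shared genes 2983, and lists in HBO vs SCI 9. With an absolute log2 fold change of 1 or more, a stricter threshold by construction, there were 2844 (2008 higher, 836 lower) and 2324 genes (1816 higher, 508 lower). The DESeq2 Wald test called 26 genes in HBO vs SCI (25 higher, 1 lower) where edgeR called 0. With an estimated correlation 0 lists passed in each comparison, and with fry 0 in HBO vs SCI. Over the 15 lists called in HBO vs SCI the estimated correlation ran from 0.14 (homeostatic microglia) to 0.9 (skeletal muscle), with 0.82 for interferon response. All lie above the preset 0.01, so the preset p values of these lists are too small if the estimates hold. Other causes of the changes in these settings were not tested.

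Of the lists called in HBO vs SCI, the medians that changed sign were those of neurons (-0.01 to 0.4 over left-out libraries), cholesterol synthesis (-0.03 to 0.32) and mitochondrially encoded genes (-0.12 to 0.69), which passed in the opposite direction, as lower, without HBO replicate 3 (adjusted p = 0.0427). Of lists not called there, those of bone and cartilage (-0.31 to 0.46, and 0.29 without HBO replicate 2, where it passed), fibroblasts (-0.29 to 0.22), phagocytes (-0.43 to 0.02), macrophages (-0.03 to 0.35), matrix proteases (-0.34 to 0.08), Schwann cells (-0.24 to 0.15), inflammasome (-0.03 to 0.25), complement (-0.14 to 0.1), apoptosis (-0.17 to 0.07), oxidative phosphorylation (-0.18 to 0.04), homeostatic astrocytes (-0.1 to 0.04), ependymal cells (-0.14 to 0.03) and neurotrophic factors (-0.07 to 0.1) changed sign. With 2 libraries per group fibroblasts were at 0.32, muscle at 0.44, mitochondrially encoded genes at -0.19, immediate early genes at 0.01, matrix proteases at 0.12, reactive astrocytes at 0.1, apoptosis and complement at 0.09, axon regeneration at 0.07, oxidative phosphorylation at 0.03 and autophagy at 0.02, each opposite in sign to the reported median. Of these, fibroblasts passed as higher (adjusted p = 0.0153) and mitochondrially encoded genes as lower (adjusted p = 0.00599), the latter against the reported call. Bone and cartilage was at 0.23 with no filter on low counts and 0.03 with the replicate block. The cause was not tested.

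With replicate number as a block, 5592 genes passed in SCI vs sham (3173 higher, 2419 lower), 0 in HBO vs SCI and 4459 in HBO vs sham (2623 higher, 1836 lower), and 24, 15 and 24 lists. Residual correlations between libraries of the same number ran from -0.18 to 0.14, and the labels do not describe a pairing. The muscle list of SCI vs sham did not pass with a mean of 5 CPM or more or with only the 2 groups compared. Size factors, filters and the 2-group fit left the counts of genes within 1.5 times those reported, and HBO vs SCI at 0 genes. A change of pseudocount was not run, and DESeq2 gives no list test here. Genes changed 1.5-fold were seldom detectable at this depth and number of libraries.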
